A study of Parhyale hawaiensis with 2 samples.

How the data were processed

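Open chromatin was profiled in single nuclei (snATAC-seq) from legs of adult Parhyale hawaiensis, a shore-dwelling amphipod crustacean with a large genome. In this assay the transposase Tn5 inserts sequencing adapters where DNA is accessible, and each droplet adds a barcode that stands for a nucleus. The labels describe 2 libraries, replicates 1 and 2, of T4 and T5 legs of an inbred line, so all samples form 1 group and no comparison between conditions exists. The labels' protocols name leg collections L1, L2 and L3 that differed in where the leg was cut (proximal end of the merus, or the basis) and in how the tissue was lysed. They do not tie these collections to the 2 libraries, and nothing says how many animals stand behind each library. The p-values of the cluster tests therefore rest on how far cluster differences vary between these 2 libraries, which may be technical. Permutation p-values rest on random placements, draws or shuffles and measure no spread between libraries.

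For each library the authors deposited a matrix of counts, a list of peaks and a list of barcodes, made with Cell Ranger ATAC 1.2.0 per the submitters' processing notes and the file headers. The deposited counts are whole numbers of transposase cut sites per peak and nucleus, neither normalized nor binarised. Between 89.1% and 90.0% of the nonzero values were even, since both ends of a fragment usually fall in the same peak. Per the file headers and the peak lists, each library has its own peaks, called over all its nuclei, and counts exist only within the peaks of that library. The peak lists give scaffold, start and end without a score. The genome build is not given in the sources used here; the scaffold names begin with phaw_50, and starts are printed 1-based. No genome or annotation was used here, so genes near peaks, motifs and cell type markers were not analysed here and clusters are called by number.

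Depth was the sum of counts in peaks per nucleus. Nuclei with fewer than 500 counts were to be left out, and none fell under that minimum. Peaks of both libraries were merged where they overlapped by at least 1 bp, and merged intervals that held at least 1 peak of each library are called shared intervals. Peak overlap and the gaps between neighbouring peaks were tested one-sided against 1000 random placements of the peaks within their own scaffold, with the largest peak end as scaffold length. Agreement between libraries was computed over shared intervals on log2(CPM + 1), where CPM, the usual scaling of counts by library total, uses the counts in peaks of the library.

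Nuclei were clustered jointly. Shared intervals were binarised and weighted by TF-IDF within each library, and a truncated singular value decomposition gave 30 components, of which 29 had a correlation with log10 depth of at most 0.5. Components were centred and scaled within each library and rows set to unit length. A graph of 20 nearest neighbours was partitioned with the Leiden algorithm at resolution 0.3 (scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2, numpy 2.4.6, scipy 1.17.1, Python 3.11.15). Shares of nuclei carry 95% Wilson intervals, which cover counting error only. A doublet score, the share of simulated doublets among 40 neighbours, was computed per library. No nucleus was removed by it in the main result.

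To keep the tested intervals apart from those that defined the clusters, scaffolds were assigned alternately to sets A (37786 shared intervals) and B (36520). Clusters were built again from set A alone and carry the number of the best matching cluster from all intervals. Counts of set B intervals were summed per library and cluster for clusters with at least 50 nuclei in both libraries. They were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F test, TMM, filterByExpr, library as a term), with Benjamini-Hochberg adjustment. An interval was called higher in a cluster at an adjusted p under 0.05 and a log2 fold change above 1. The fold change is against the mean of the other clusters on the log scale, which clusters with few counts pull down. The adjustment runs within each cluster's contrast, not over the 16 contrasts. Where other clusters hold no count, a log2 fold change depends on the small prior edgeR adds, so CPM values are printed beside it. The mean CPM printed for the other clusters is arithmetic, so its ratio can be smaller than the fold change. Counts were also simulated with the means and library sizes of the data, with intervals of higher counts raised in cluster 5 (25520 intervals tested). At an adjusted p under 0.05 and without a minimum fold change, 100 of 100 raised 4-fold and 54 of 100 raised 2-fold were recovered. The simulated spread (dispersion 0.05) was below that fitted to the data (common dispersion 0.0905), so recovery in the data may be lower. Of the unchanged intervals, 2 of 25320 were called. Grouping the nuclei at random 5 times gave 0 intervals differing between groups by the edgeR F test and at most 3 called higher in a group, of 30482 tested.

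Co-accessibility was the Pearson correlation of log2(CPM + 1) between intervals of set B over groups of 50 nuclei that neighbour each other in the set A components, in each library alone. It used 8701 intervals with at least 500 counts in each library and at most 2000 pairs per distance bin. Each bin was compared with 1000 draws of partners from other scaffolds matched on decile of counts, with adjustment over the 9 bins of both libraries. The correlation step was also run on simulated noise with planted identical profiles, which checks the computation only.

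Intervals named in the text follow a rule set before the data were examined. It takes the 5 shared intervals open in the largest share of nuclei; the top 2 set B intervals per tested cluster by log2 fold change among those that passed, that were higher than in every other cluster in both libraries and that had at least 50 counts; the 2 intervals with the largest CPM ratio between libraries in each direction, among those with at least 1000 counts; and the 3 scaffolds with the most shared intervals per Mb. Alternatives covered depth minimums, overlap rules, pseudocounts, clustering settings, doublets, the library term, normalization, filters, DESeq2 1.42.0, group sizes and thinning. Leaving out a replicate leaves no residual degrees of freedom for the cluster tests, so no test was made that way.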

Results

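The series maps open chromatin across the large genome of Parhyale hawaiensis in order to find regulatory elements. The data are 2 snATAC-seq libraries from adult T4 and T5 legs, replicates 1 and 2 of a single group. Replicate 1 held 7951 nuclei with 40098991 counts in peaks, and replicate 2 held 8018 nuclei with 39132472. The median nucleus had 3711 counts in replicate 1 (quartiles 2504 and 5842) and 4235.5 in replicate 2 (quartiles 2707 and 6090).

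Peaks covered a small part of the scaffold span and lay closer together than after random placement. Replicate 1 had 90954 peaks that covered 55.4 Mb, 2.55% of the 2169 Mb spanned by peaks on 99 scaffolds. Replicate 2 had 94412 peaks that covered 57.7 Mb, or 2.66%. The median peak was 451 bp wide in replicate 1 and 444 bp in replicate 2. Neighbouring peaks were separated by a median of 5515 bp in replicate 1 and 5974 bp in replicate 2, against 15008 bp and 14582 bp after random placement within scaffolds (permutation p = 0.000999 in each library, the smallest that 1000 placements can give). Placement was uniform along scaffolds and did not leave out stretches where no peak could be called, since no genome was used. In replicate 1, 47.7% of gaps between neighbouring peaks were under 5 kb, while 5.12% exceeded 100 kb. The density of shared intervals ranged from 10.6 per Mb on scaffold phaw_50.283743c to 63.4 on phaw_50.000214d, around a median of 32.7 over the scaffolds. The densest after phaw_50.000214d were phaw_50.000214f with 62.5 per Mb and phaw_50.283869b with 61.2 per Mb.

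Most open regions were found in both libraries. Of the peaks of replicate 1, 83.0% overlapped a peak of replicate 2, against a mean of 5.61% after random placement. Of the peaks of replicate 2, 79.8% overlapped a peak of replicate 1, against 5.41% (permutation p = 0.000999 for both, one-sided, the smallest possible). Merging gave 74306 shared intervals, which held 97.5% of the counts of replicate 1 and 97.3% of those of replicate 2. Peaks found in replicate 1 alone were narrower (median 213 bp against 500 bp) and held fewer counts (median 51 against 242) than its overlapping peaks. The same held in replicate 2, with 264 bp against 507 bp and 45 counts against 212.

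A few wide intervals were open in most nuclei of both libraries. The interval at phaw_50.282396b 7063974 to 7085562, 21589 bp wide, was open in 79.5% ± 1.86 of nuclei (SD, n = 2). An interval of 2876 bp at phaw_50.283815a 1342575 to 1345450 was open in 74.998% ± 0.817, and its neighbour on the same scaffold at 1348844 to 1353778 in 64.6% ± 4.44. The others of the top 5 were phaw_50.283828b 8768576 to 8793468, open in 65.6% ± 1.33, and phaw_50.282654b 24053804 to 24067770, open in 64.9% ± 0.421. The share varied between clusters, taken in each library on its own and without correction for depth. The interval on phaw_50.283828b ranged from 13.8% to 85.5% of nuclei over the tested clusters of either library, and the one on phaw_50.282396b from 61.8% to 87.2%. Median depth was as low as 1936 counts in cluster 19 and 2162.5 in cluster 9 of replicate 2, so these ranges do not separate clusters from depth. At a lower level, 102 of the tested set B intervals were open in at least 30% of nuclei, with a median width of 3390 bp.

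Accessibility summed over all nuclei was similar in the 2 libraries, apart from a small set of intervals. Across shared intervals the Pearson correlation of log2(CPM + 1) was 0.91995 and Spearman's rho 0.907; intervals are not independent replicates. Of 19856 intervals with at least 1000 counts, 97.0% lay within 2-fold and 55 differed over 4-fold. The interval at phaw_50.282396b 7288430 to 7293523 had 22 counts in replicate 1 and 1085 in replicate 2, and that at phaw_50.000135b 6943500 to 6945621 had 156 and 2510. In the other direction, phaw_50.283867b 24901969 to 24906153 had 1517 counts in replicate 1 and 57 in replicate 2, and phaw_50.283828a 32589400 to 32593459 had 1722 and 99. In each of these the direction was the same in all 17 clusters present in both libraries. Counts were taken over unequal lengths, however: the called peak at phaw_50.282396b spanned 83 bp in replicate 1 and 5094 bp in replicate 2, and per bp of peak its log2 ratio turned from -5.66 to 0.28, in favour of replicate 1. At phaw_50.283867b the peaks spanned 4185 bp and 213 bp, and the log2 ratio per bp was 0.40 instead of 4.70. At phaw_50.000135b, with 346 bp and 2122 bp, it stayed in favour of replicate 2, at -1.43 instead of -4.05.

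The nuclei formed 21 clusters, of which 17 had at least 50 nuclei in both libraries. In 16 of these the shares of the 2 libraries were within 1.60-fold, and cluster 14 held 1.36% of replicate 1 and 4.98% of replicate 2. With each library clustered alone, 12 clusters matched reciprocally, of 21 in replicate 1 and 23 in replicate 2, and those without a match held 42.0% and 45.4% of nuclei. Cluster 2 held 11.8% of nuclei of replicate 1 (95% Wilson interval 11.1 to 12.5) and 11.7% of replicate 2 (10.99 to 12.40). Cluster 1 held 11.1% (10.4 to 11.8) and 13.8% (13.02 to 14.53). Cluster 11 held 4.07% (3.66 to 4.53) and 4.10% (3.69 to 4.56), and cluster 20 held 1.84% (1.56 to 2.16) and 1.93% (1.65 to 2.26). Clusters 6 and 13 came almost wholly from replicate 1, with 912 nuclei against 16 and 513 against 1, which is 11.47% against 0.200% and 6.45% against 0.0125%. Clusters 12 and 21 came almost wholly from replicate 2, with 599 nuclei against 4 and 254 against 12. Clusters 12 and 21 depended on the settings. With every nucleus thinned to 1500 counts, which left out 794 nuclei of replicate 2 and 1 of replicate 1, their Jaccard indices were 0.105 and 0.0702, while with replicate 2 clustered alone they were 0.602 and 0.718 and with joint centring 0.960 and 0.779. Cluster 14 depended on them too, with an index of 0.148 after thinning and 0.155 against its best match among clusters built from set A. Clusters 6 and 13 had indices of 0.870 and 0.769 after thinning, and 0.905 and 0.563 with replicate 1 clustered alone. Other clusters also moved under some settings. Cluster 20 had an index of 0.363 after thinning, and cluster 19 had 0.252 against clusters built from set B. With replicates 1 and 2 each clustered alone, cluster 1 had 0.301 and 0.181 and cluster 2 had 0.392 and 0.286. No test was made on shares, since both libraries belong to 1 group.

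**Figure D1:**
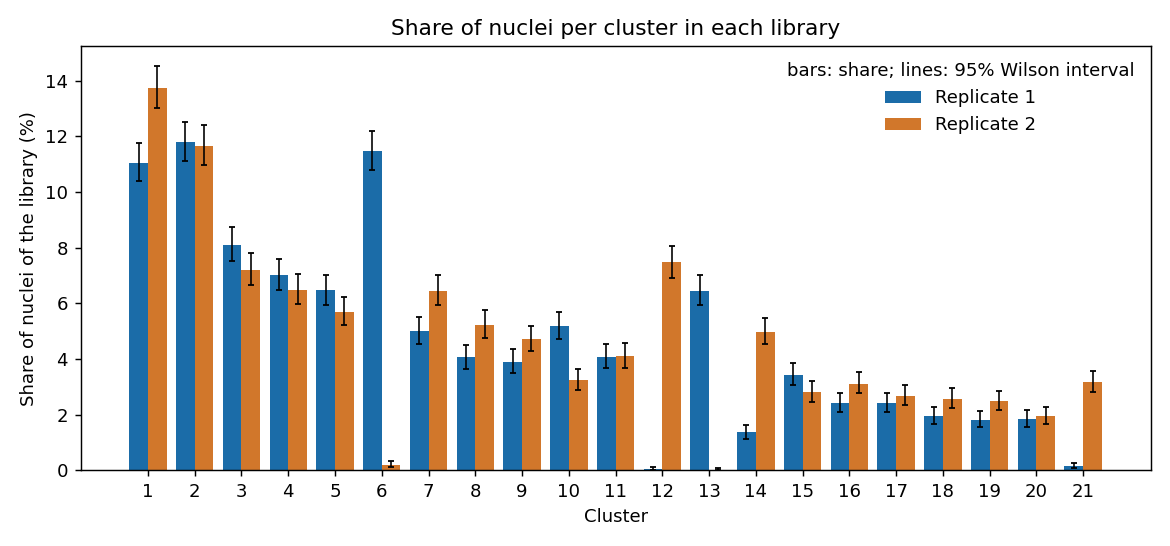
Share of nuclei of each library (percent, y axis) in each of the 21 clusters (x axis); bars are replicates 1 and 2 and lines are 95% Wilson intervals. Clusters 6 and 13 hold 11.47% and 6.45% of replicate 1 and under 0.3% of replicate 2.

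Most open regions differed in accessibility between groups of leg nuclei. Clusters built from scaffold set A were compared at intervals of set B, with 16 clusters present in both libraries. Of 31377 intervals tested, 22538 (71.8%) differed between clusters at an adjusted p under 0.05 (edgeR quasi-likelihood F test), and 22600 were higher in at least 1 cluster by the contrasts of single clusters. Higher accessibility in exactly 1 cluster was found for 8263 intervals and in 4 or more for 2269. Cluster 2 had the most higher intervals (6628), while cluster 20 had 1047 and cluster 7 had 1019. Detection depends on the counts behind each cluster, so these numbers do not compare clusters at equal power. Cluster 20 as built from set A had 156 nuclei of replicate 1 and 154 of replicate 2. As built from set A, cluster 2 was larger than described above, with 1085 nuclei of replicate 1 and 1866 of replicate 2, of which 59.8% lay in cluster 2 of all intervals; for cluster 1 that share was 76.0%. Cluster 9 had 1318 intervals that were higher there and in no other tested cluster, cluster 11 had 1131, and cluster 15 had 84. The count for cluster 7 was the least settled: it was 43 without the library term and 3342 without the nuclei with the highest doublet scores.

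Some clusters shared many of their higher intervals. Clusters 16 and 20 had 549 in common where 49.0 would be shared by independence, a ratio of 11.2. All pairs among clusters 5, 10, 15, 16 and 20 had higher ratios than any other pair, from 4.80 for clusters 5 and 16 upward. Next came clusters 2 and 17 with 3.74, clusters 3 and 4 with 3.18, clusters 4 and 8 with 3.08, clusters 11 and 18 with 3.06, clusters 1 and 2 with 2.91 and clusters 1 and 17 with 2.39. These did not form closed sets. The ratio was 2.25 for clusters 7 and 17 and for clusters 18 and 19, 2.16 for clusters 2 and 7, and 2.04 for clusters 1 and 3. It was 1.92 for clusters 8 and 15, 1.86 for clusters 1 and 7 and 1.85 for clusters 3 and 8. Between clusters 1, 2 and 17 and clusters 5, 10, 15, 16 and 20 the ratio ranged from 0.0789 for clusters 1 and 5 to 0.327 for clusters 16 and 17. Contrasts against the mean of the other clusters lower such ratios by construction, and neighbouring intervals are not independent, so no p-value is given. A ratio also cannot exceed the number of intervals tested over the larger of the 2 sets. No pair with cluster 2 (6628 higher) could therefore reach 4.80, so the ranking of pairs partly follows from set size. Clusters 2 and 17 shared 3355 of the 4249 intervals higher in cluster 17. Clusters 16 and 20 shared 549 of the 1047 higher in cluster 20.

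**Figure D2:**
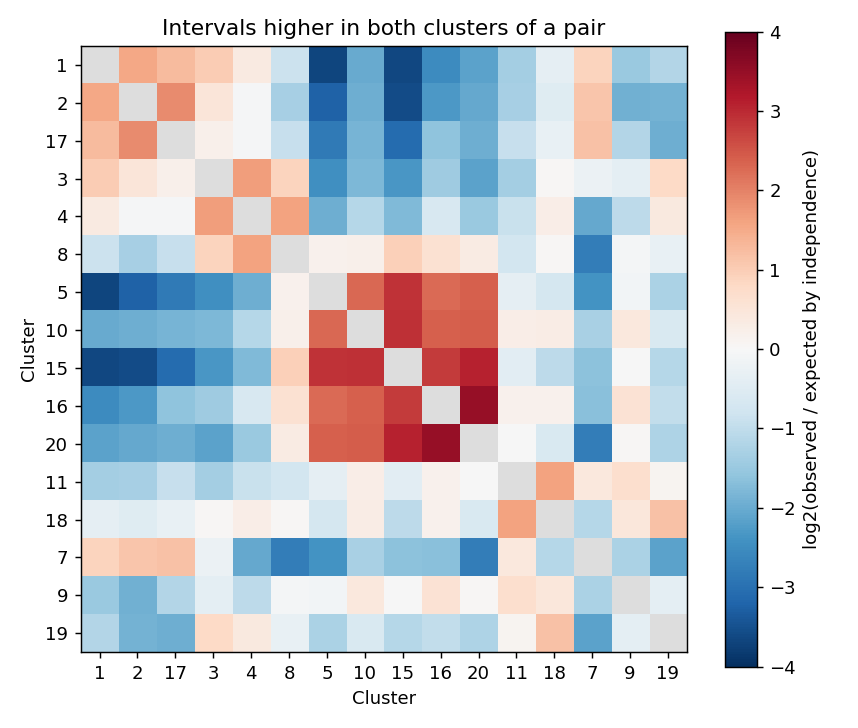
For each pair of tested clusters (both axes), colour gives log2 of the number of set B intervals higher in both over the number given by independence; grey marks a cluster with itself. Clusters 5, 10, 15, 16 and 20 form a block of high ratios, with 11.2 for clusters 16 and 20 before taking the log. The highest possible ratio is lower for clusters with more higher intervals.

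Each of clusters 5, 10, 15, 16 and 20 also had intervals of its own. Cluster 16 was marked by phaw_50.283869c 2347299 to 2348186, open in 33.7% of its nuclei in replicate 1 and 51.0% in replicate 2. Its CPM in cluster 16 was 306.3 ± 168.0 (SD, n = 2) against an arithmetic mean of 1.93 in the other clusters. The log2 fold change against their mean on the log scale was 8.55 (edgeR adjusted p = 7.62e-19). In cluster 20 the interval at phaw_50.015400a 22606559 to 22606845 had a CPM of 100.6 ± 26.6 against 0.724 (log2 fold change 8.48, edgeR adjusted p = 4.76e-18). In cluster 10, phaw_50.283826 26923605 to 26924053 had a CPM of 104.8 ± 1.84 against 1.04, and phaw_50.000135e 1519389 to 1519804 had 67.4 ± 20.8 against 0.932. Both leading intervals of cluster 15 lay on phaw_50.283828a, at 24035639 to 24035890 and at 24185987 to 24186282, with a CPM of 84.1 ± 11.4 at the latter against 0.548. The leading interval of cluster 5, phaw_50.283852 1324308 to 1324636, had a CPM of 38.1 ± 8.57 against 0.940. The next one in cluster 5, phaw_50.283817e 6026671 to 6027053, was also open in cluster 15, at 27.6 CPM against 27.7 in replicate 1 and 18.5 against 36.4 in replicate 2.

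Among clusters 1, 2 and 17, the named intervals had a lower CPM in the larger clusters. The naming rule asks for at least 50 counts, which is a higher CPM in a small cluster, so the rule partly fixes this pattern. The top interval of cluster 1, phaw_50.000135f 28231686 to 28232147, had a CPM of 20.4 ± 7.74 against a mean of 1.07 elsewhere (log2 fold change 5.64, edgeR adjusted p = 1.36e-10). That of cluster 2, phaw_50.282275a 10143371 to 10143690, had 10.8 ± 1.05 against 0.612. In cluster 17, with 2.41% and 2.68% of nuclei, phaw_50.015400b 4847020 to 4847430 had 67.8 ± 36.7 against 0.854. There phaw_50.283850a 10147338 to 10148319 was open in 17.4% and 31.6% of nuclei. Cluster 17 had 226 intervals higher there and in no other tested cluster, against 848 in cluster 1 and 715 in cluster 2. The top interval of cluster 8, phaw_50.283865b 9893897 to 9894194, had 56.5 ± 10.1 against 1.03 (log2 fold change 7.25, edgeR adjusted p = 4.72e-16), and its next one, phaw_50.000289b 1590344 to 1590819, had 116.4 ± 15.5 against 2.06 (log2 fold change 6.71, edgeR adjusted p = 1.92e-20). The top interval of cluster 3, phaw_50.283850a 16436910 to 16437282, had 30.6 ± 1.93 against 0.981, and that of cluster 4, phaw_50.283828a 30022596 to 30022844, had 33.7 ± 2.27 against 0.648.

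Clusters 9, 11, 18 and 19 were each marked by intervals with low counts elsewhere. Cluster 18 had phaw_50.283868d 6643786 to 6644162, with a CPM of 161.5 ± 55.2 against 0.905 (log2 fold change 8.59, edgeR adjusted p = 2.98e-20). In cluster 11, phaw_50.282976b 2470544 to 2470958 had 76.3 ± 19.7 against 1.32. In cluster 19, phaw_50.020523d 2792186 to 2792489 had 54.8 ± 5.17 against 0.312; no cluster built from set B matched cluster 19. In cluster 9, phaw_50.283562a 11552533 to 11552850 had 31.9 ± 9.89 against 0.246. The leading interval of cluster 9, phaw_50.000214f 8547273 to 8547753, varied more between libraries (50.3 ± 44.0) and did not pass with DESeq2 (adjusted p = 0.377). Nor did phaw_50.283826 1436693 to 1437031 in cluster 11 (DESeq2 adjusted p = 0.0629) and phaw_50.283828a 24035639 to 24035890 in cluster 15 (DESeq2 adjusted p = 0.143). Cluster 7 had no interval of comparable contrast: in replicate 1, 1 of its 10396 intervals with at least 100 counts exceeded every other cluster over 2-fold. It also had the largest share of nuclei with top doublet scores among the tested clusters, 26.2% in replicate 1 and 14.7% in replicate 2. Its top interval, phaw_50.283868d 4209753 to 4210180, had 9.11 ± 3.61 against 1.45 (log2 fold change 2.94, edgeR adjusted p = 0.00927), and without the library term it no longer passed (edgeR adjusted p = 0.0805). The same held for phaw_50.283861b 14188417 to 14188836 (edgeR adjusted p = 0.0736 without the library term).

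**Figure D3:**
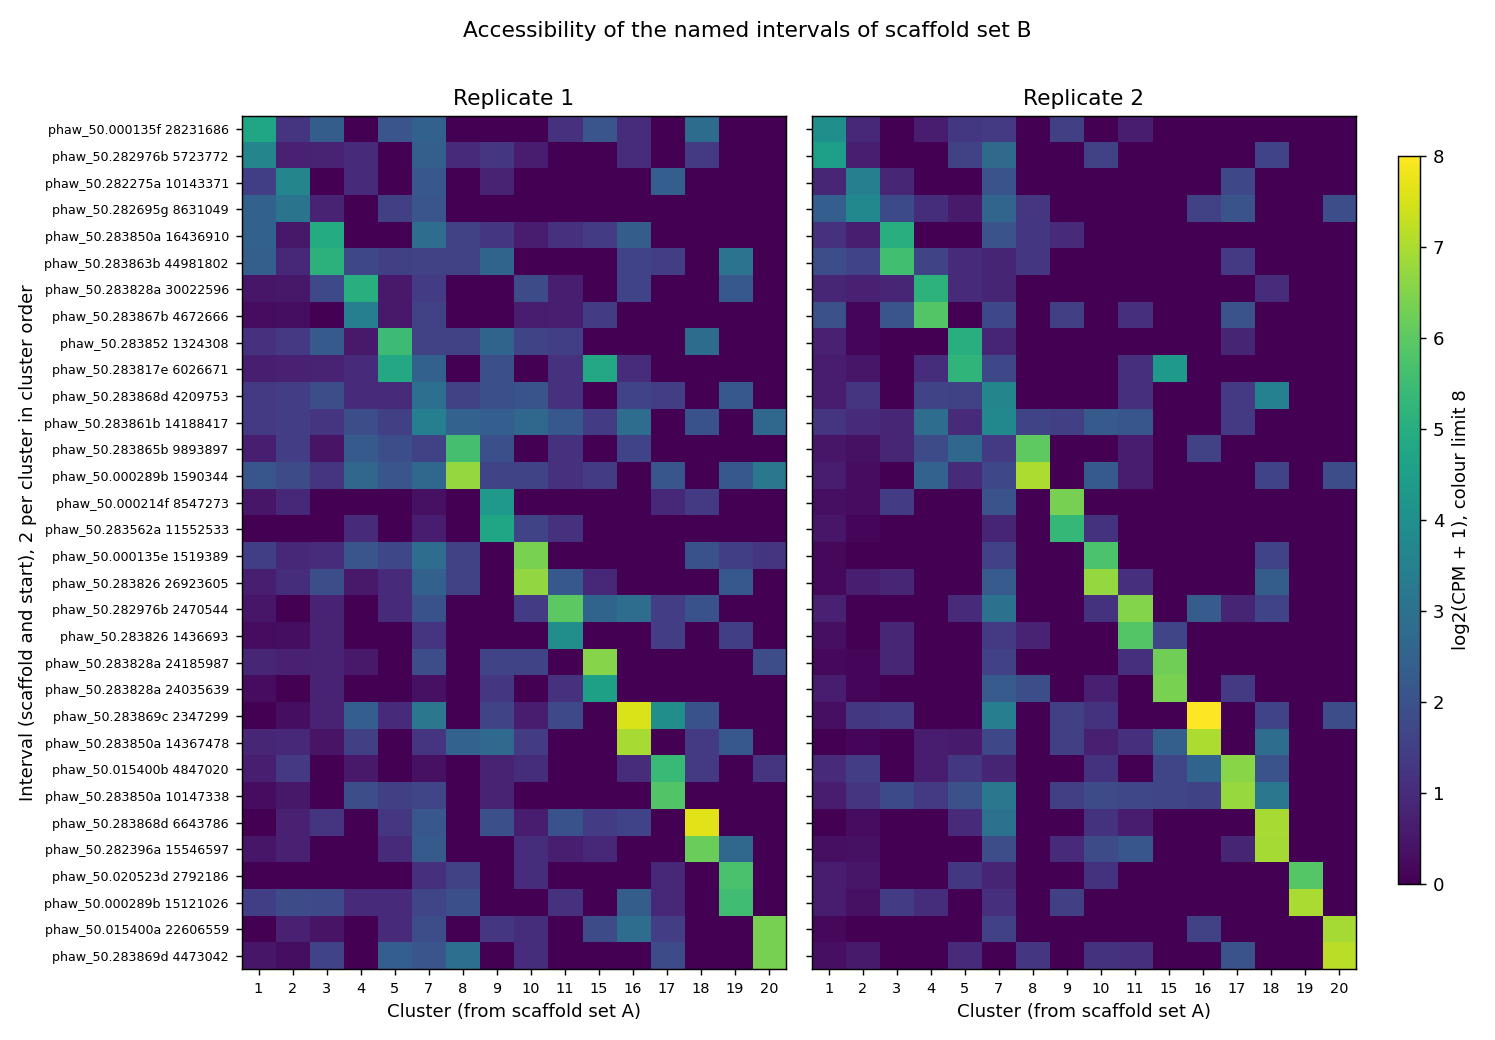
log2(CPM + 1) of the 32 named set B intervals (rows, labelled by scaffold and start) in the 16 tested clusters (columns), for each library; rows follow the cluster each interval was chosen for, so high values lie on the diagonal. The interval of cluster 16 at phaw_50.283869c reaches a mean CPM of 306.3, and cluster 7 shows low levels at many intervals of other clusters.

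Intervals on the same scaffold varied together across groups of nuclei over long distances. Pairs within 5 kb had a mean correlation of 0.240 in replicate 1 and 0.289 in replicate 2, against 0.0339 and 0.0521 for matched pairs on different scaffolds. At 20 to 50 kb it was 0.128 and 0.153, and at 100 to 200 kb 0.0871 and 0.109. From 200 to 500 kb the excess over matched pairs had shrunk to 0.0233 and 0.0192. At 1000 to 5000 kb it was 0.0113 and 0.0124, still above the matched pairs in both libraries (permutation p = 0.0030 and 0.0050, adjusted p = 0.00317 and 0.0050). All 9 distance bins exceeded their matched pairs in both libraries, the other 8 at the smallest p that 1000 draws allow. The share of pairs with a correlation above 0.5 fell from 12.7% within 5 kb to 1.2% at 1000 to 5000 kb in replicate 1, and from 20.7% to 3.15% in replicate 2. Pairs of intervals are not independent, and the correlations depend on the size of the groups of nuclei. The groups were drawn from all clusters, so the correlations include differences between clusters. Both libraries were tested at the same pairs, so they are not independent samples of pairs.

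**Figure D4:**
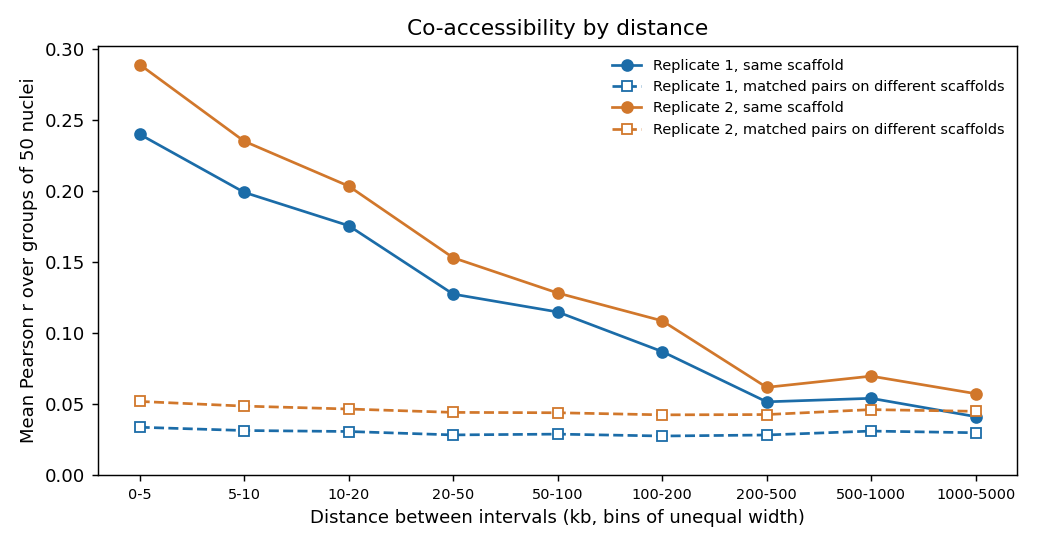
Mean Pearson correlation between intervals over groups of 50 nuclei (y axis) by distance between the intervals in kb (x axis, bins of unequal width); filled symbols are pairs on the same scaffold and open symbols matched pairs on different scaffolds, in each library. The correlation falls from 0.240 and 0.289 within 5 kb toward the matched level.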

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

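Among the tests below, those on thinning, on profile likelihood, on cluster shares, on widened peaks, on counts per bp and on free chromatin were chosen only after the result was seen, and so was the rule that weighs free chromatin against intervals of clusters 5 and 10.

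Counts in peaks called in a single library are listed here because the comparisons, which used shared intervals, left them aside: 1021434 counts in peaks of replicate 1 alone and 1051509 in peaks of replicate 2 alone. Such peaks hold counts by construction, and no test was made on them. In replicate 1 they made up 3.14% of the counts of cluster 6 and 3.46% of cluster 13, the highest shares of its clusters, against 1.81% in cluster 2. In replicate 2 the shares were 2.35% in cluster 12 and 2.27% in cluster 21, which it held almost alone, against 4.74% in cluster 7, 3.81% in cluster 9 and 3.79% in cluster 11, which both libraries shared. The top peak of replicate 1 alone, phaw_50.283850a 18111345 to 18115389, had 2441 counts, of which 49.5% came from cluster 6.

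Clusters 6 and 13 held nuclei of replicate 1 almost only. Doublets were argued against by intervals with at least 100 counts that exceeded every other cluster of replicate 1 over 2-fold. They numbered 339 of 13430 in cluster 6 and 549 of 9017 in cluster 13, against 1 of 10396 in cluster 7. These same intervals had helped to build the clusters, which limits the argument. A low number alone would not mark doublets, since clusters 14 and 19 had 8 each, of 209 and 312. Depth was argued against too, since the lower Jaccard index after thinning was 0.769. Matching nuclei of replicate 2 hidden by centring within each library were argued against as well: 0 of 8018 were most likely under either profile (up to 0.0374% is allowed by counting), while 91.3% and 88.9% of left-out nuclei of these clusters in replicate 1 found their own profile; cluster 14 shows the limit of this test, as 7.41% of its left-out nuclei of replicate 1 and 0% of its nuclei of replicate 2 found it, against 75.3% to 98.1% of nuclei of replicate 2 in the 16 other clusters found in both. That argument rests on the later test: in the one set beforehand, a marker score, 9.53% of nuclei of replicate 2 reached the level of cluster 6, over the 5% set in favour of hidden nuclei, but so did 14.2% of the nuclei of replicate 1 outside it (2.22% and 3.28% for cluster 13). The leg part taken, the animals and the lysis could differ between the libraries, which is untested because the labels do not tie the collections to them.

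Of the 55 intervals over 4-fold apart between libraries, 36 kept their direction in all 17 clusters found in both. Cluster shares as weights in the pooled counts were argued against, since the median log2 ratio was still 2.17 (quartiles 1.85 and 2.50) with equal weight per cluster, against 2.29 as pooled. That does not cover clusters 6 and 13 widening the peaks called in replicate 1, which stays open: 58.6% of the 29 intervals higher in replicate 1 had their highest CPM there in cluster 6 or 13, against 9.20% of all intervals with at least 1000 counts. Different peak boundaries could account for part and cannot be told apart from a difference in accessibility, because counts exist only within each library's own peaks: per bp of peak the median log2 ratio was 0.93 (quartiles 0.44 and 1.26), 1 of the 55 had peak widths within 1.5-fold, and among intervals with at least 1000 counts 21.4% differed over 2-fold where widths were further apart and 1.47% where they were not. No biological explanation was tested.

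Intervals that mark cluster 6 carried counts in other clusters of replicate 1. They were higher there than in replicate 2 in 16 of 17 clusters, with a median excess of 4.66% of the level in cluster 6, as free chromatin in the suspension might give. Intervals that mark clusters present in both libraries were also higher in replicate 1, in 16 of 16 clusters for cluster 5 (median excess 1.52%) and in 12 of 16 for cluster 10 (0.653%), and those of cluster 13 in 16 of 17 (2.87%). Of these 4 sets the excess was largest for cluster 6, but its direction was not specific to it, so free chromatin stays open. Peaks called wider in replicate 1 could also give an excess there, since counts exist only within each library's own peaks. The peak widths of these 4 sets were not compared between the libraries, so wider peaks stay open as well. Doublets with nuclei of cluster 6 stay open too, as the variance of open marker intervals per nucleus over its mean was 1.26 (median over clusters), between the levels set for and against them, with 3.46 for intervals of cluster 5, 2.13 for cluster 10 and 1.18 for cluster 13.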

How the results depend on the processing

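Alternatives chosen only after seeing the data were centring over both libraries together, thinning nuclei to 1500 counts, adding clusters found in 1 library to the fit, counts per bp and equal cluster weight; the others were planned.

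Intervals differing between clusters numbered 19086 to 24512 over 8 alternatives against 22538, and intervals higher in at least 1 cluster 18136 to 25347 over 9 alternatives against 22600; without the library term (no replicate block) they were 19086 and 20906. Peak overlap, spacing, depth and all 54 co-accessibility alternatives kept their direction and side of the threshold, although merging peaks closer than 500 bp and requiring 50 peaks per scaffold changed nothing and so tested nothing. The agreement between libraries moved to 0.866 with a pseudocount of 0.1 and to 0.975 as share of nuclei open. Clusters with at least 90% of nuclei from 1 library numbered 4 in the main result, 8 at resolution 0.6, 2 with 15 components, 8 with joint centring and 2 after thinning. Nuclei of replicate 2 in its own clusters moved from 10.6% to 0% with 15 components, 0% after thinning, 6.78% with another seed and 30.4% with joint centring. With each library clustered alone, 12 clusters matched reciprocally, and clusters without such a match held 42.0% of nuclei of replicate 1 and 45.4% of replicate 2; the main shares were 17.9% and 10.6%. Thinning left out 794 nuclei of replicate 2 and 1 of replicate 1. Per bp of peak the log2 ratio at phaw_50.282396b 7288430 reversed from -5.66 to 0.28; at phaw_50.283867b 24901969 it moved from 4.70 to 0.40 and at phaw_50.283828a 32589400 from 4.08 to 0.67, while phaw_50.000135b 6943500 kept its direction, from -4.05 to -1.43. Without the 5% of nuclei with the most counts, 3 of the 5 most open intervals moved beyond their SD, to between 63.3% and 73.9% of nuclei. For the other moves the cause was not tested.

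Of 185 recomputed values of the 32 intervals named for clusters, 180 kept their call, 5 lost it and 0 changed sign; 7 more, at intervals of clusters 1, 2 and 7, gave no value because the interval was filtered out or given no adjusted p. Of 127 recomputed counts per cluster, 9 moved over 1.5 times, 8 of them in cluster 7, from 1019 to between 43 and 3342, and 1 in cluster 20, from 1047 to 1588 with the scaffold sets exchanged, where cluster 19 had no match and so no count. No paired analysis between groups was possible because the series has 1 group. Positions relative to genes and motifs, with their alternatives, were not run, as no genome was used here. Tests without replicate 1 or 2 were not possible, since 1 library leaves no residual degrees of freedom. At the depth of cluster 5, and with a lower dispersion than in the data, simulated 4-fold changes were recovered for 100 of 100 intervals. Simulated 2-fold changes were recovered for 54 of 100. Other clusters were not simulated.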

Other observations

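No test of this part was chosen only after the result was seen; the intervals of clusters 6 and 13 and the widths were picked after their values were seen and are untested.

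Cluster 13 had the most contrasted intervals among the clusters found in replicate 1 alone. The interval at phaw_50.283355a 10897517 to 10898392 had a CPM of 124.7 in cluster 13 against at most 11.47 in any other cluster of replicate 1, and over all nuclei 16.4 in replicate 1 and 4.60 in replicate 2. At phaw_50.283828b 10125602 to 10126097 it was 56.0 against at most 5.34 in another cluster, yet over all nuclei it was 6.61 in replicate 1 and 6.85 in replicate 2, which held 1 nucleus of cluster 13. In cluster 6, phaw_50.283815c 30156988 to 30157694 had a CPM of 51.6 against at most 8.65 in another cluster. These intervals were picked for their contrast and have 1 library behind them, so no test was made. The profile of cluster 6 correlated most with cluster 2 in replicate 1 (r = 0.648) and that of cluster 13 with cluster 1 (r = 0.640).

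Interval width and openness varied with the number of clusters in which an interval was higher. The median width was 760 bp for intervals higher in no cluster, 522 bp for 1 cluster, 580 bp for 2 or 3 and 774 bp for 4 or more. The median share of nuclei in which they were open was 2.06%, 1.23%, 1.80% and 3.78%.

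A hypothesis was that neighbouring open regions tend to be higher in the same cluster beyond chance placement. Of 11781 neighbouring pairs within 10 kb in which both were called, 65.9% shared at least 1 cluster, against a mean of 27.1% and at most 28.6% over 1000 shuffles of the calls over tested intervals (permutation p = 0.000999, the smallest possible). At 10 to 50 kb the share was 60.9%, and at 50 to 200 kb it was 52.2%. Chance placement was thus argued against; domains of shared regulation may give such a pattern, and this was not tested.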
